A study of Arabidopsis thaliana with 40 samples.

How the data were processed

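Transcript levels were measured with Affymetrix 3′ expression arrays in leaves of Arabidopsis thaliana, Columbia wild type and 3 mutant genotypes, after 4 d of moderate light with drought (MLD, about 350 µE light, no water) or of continued standard growth (untreated, 100 µE light). Biotin-labelled cRNA was prepared by the standard Affymetrix method, per the labels' protocols. Whether such arrays report levels of plastid and mitochondrial transcripts as they do those of nuclear genes was not tested. The 40 arrays form 16 groups in 3 sets. Each set holds a mutant and the wild-type arrays that the labels name as its control: 14 arrays for aox1a, 14 for rpoTmp and 12 for the aox1a:rpoTmp double mutant. Each single mutant has 2 lines with 2 arrays per line and treatment. Wild type and double mutant have 3 arrays per treatment in each set.

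The authors deposited 1 table of intensity values, on a linear scale, for 22810 probe sets. Per the submitters' processing notes, Affymetrix Expression Console, MAS5, Partek 6.5 and GCRMA were used. The notes give no roles or order for these tools. Array medians lie between 23.3 and 26.9 and upper quartiles between 151 and 173, so the arrays share a common scale. Whether the 3 sets were hybridised or normalised together is not given in the sources used here. Lower quartiles lie between 5.54 and 6.09 and the lowest value of an array between 2.66 and 3.12, so many probe sets sit near the floor. There a fall cannot be followed, and the size of a rise from the floor is not exact.

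The analysis plan, with its comparisons, gene lists, alternatives and rule for named genes, was fixed before the data were examined. It assumed values on a log2 scale. The deposited intensity values were linear, so log2 was taken with no pseudocount (lowest value 2.66). The 64 control probe sets were left out of all tests, which leaves 22746. Probe sets were named through the table that pairs them with genes: 13513 with a single gene, 503 with several and 8730 with none. Of the 13513, 13436 matched the TAIR10.1 gene table by identifier, which was used for names only. No genome build is given for the arrays and no coordinates are printed. Where a gene had several single-gene probe sets (147 genes), the one with the highest mean over the 40 arrays stood for it.

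Each set was fitted alone with limma 3.58.1 in R 4.3.3, with 1 coefficient per group. The lines of a single mutant were averaged with equal weight. Comparisons were the wild-type stress response, the mutant against wild type untreated and under MLD, the mutant stress response, and their interaction. The effect of the double mutant against that of each single mutant was tested in a fit of all 40 arrays, with each mutant first compared with the wild type of its own set. This makes 19 comparisons. A probe set was called with a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Log2 changes are given with their standard error (SE) from the fit, and group means with the standard deviation (SD).

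Genes were named by rule. For each main comparison these were up to 10 single-gene probe sets with the largest rise and up to 10 with the largest fall, among those called, with a mean log2 of at least 5 in the higher group and no overlap between the arrays compared. Up to 5 each way were taken for interactions and differences between mutants. Up to 2 members each way were taken from every gene list. The text prints a selection of the genes the rule names, and 1 probe set without a listed gene that was chosen after its values were seen. Of 25 lists, 23 were written from general knowledge and 2 hold the plastid-encoded and the mitochondrially encoded genes that the gene table matches. The lists cover mitochondrial stress response, alternative respiration, organellar transcription, nuclear subunits of complexes I and IV, mitochondrial import and nuclear photosystem genes. They also cover carbon fixation and electron transport, chlorophyll biosynthesis, drought and abscisic acid, oxidative and high light stress, and flavonoid and anthocyanin biosynthesis. Further lists cover heat shock, salicylic acid, jasmonate, glucosinolates, senescence, flowering, the circadian clock, and markers of floral organs, dividing cells, guard cells and phloem. Only 18.4% of the 397 list entries had a single-gene probe set, so a list stands for its measured members alone. The mitochondrial stress and alternative respiration lists share NDB2 and NDB4. 1 locus of the complex I list was left out because the gene table gives it a symbol other than the one in the list. Whether both symbols mean the same gene was not settled, so that list can lack a true member. The 12 lists with at least 3 measured members were tested with camera in limma (preset correlation 0.01, adjusted over the lists of a comparison), again with an estimated correlation, and with fry. Members were counted over all probe sets and adjusted over the list alone.

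The fit was tested on simulated data for 22746 probe sets. Of 100 changed by log2 1 it recovered 60 in the untreated comparison of aox1a, 60 in that of rpoTmp and 73 in that of the double mutant. Of 100 changed by log2 2 it recovered 88, 95 and 94. False calls were 11 of 159, 14 of 169 and 11 of 178. The changed probe sets were drawn from those with a mean log2 of at least 5. The simulated noise was independent between probe sets and held no deviating array. These rates do not extend to dim probe sets or to data with such an array. The number of arrays limits the precision of every value.

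Alternatives were quantile normalisation, a filter on probe sets with a mean log2 under 5, array weights, trend and robust moderation, a fit of all 40 arrays, a replicate term, pooled or single lines, and omission of each array in turn. After the data were seen, list tests and overlaps were also run without wild-type untreated replicate 2 of the aox1a set. No deposited array was left out of the main analysis.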

Results

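Leaf transcript levels were measured on 40 arrays from wild-type Arabidopsis (Columbia), aox1a, rpoTmp and the aox1a:rpoTmp double mutant. AOX1A is the main leaf form of the mitochondrial alternative oxidase, which takes electrons from ubiquinol past the cytochrome pathway. RPOTMP is a phage-type RNA polymerase of mitochondria and plastids. The question, as far as the labels give it, is how each mutation alters transcript levels in untreated plants and under combined moderate light and drought (MLD). The labels disagree on plant age. For the double set the sample characteristics give 5 weeks untreated and 4 weeks under MLD, the source names give 4 weeks, and the growth protocol gives 6 to 7 weeks for the double mutant. For rpoTmp they give 5, 4 and 5 weeks, and for its wild type 4 weeks in all sources, so this mutant and its wild type differ by a labelled week in some of them. Arrays separated by set. By treatment they separated except in the double mutant and for 1 untreated wild-type array of the aox1a set. The first principal component held 47.6% of the variance and the second 17%. On the first, the double mutant lay at -73.03 to -60.85 untreated and at -65.03 to -50.49 under MLD. Between the untreated wild types of the 3 sets, 6790 to 10728 of 22746 probe sets differed. The 6790 lie between the aox1a and rpoTmp sets, whose wild types are labelled 4 weeks in all sources. There, set and any batch of arrays cannot be told apart. In the contrasts with the double set, labelled age cannot be told apart from them either. Each mutant is therefore compared with the wild type of its own set. This does not remove the labelled age differences within the rpoTmp and double sets. Between lines of a mutant, with 2 arrays per line and treatment, few differences were called: 8 and 28 probe sets were called between the aox1a lines, untreated and under MLD, and 22 and 38 between the rpoTmp lines.

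**Figure D1:**
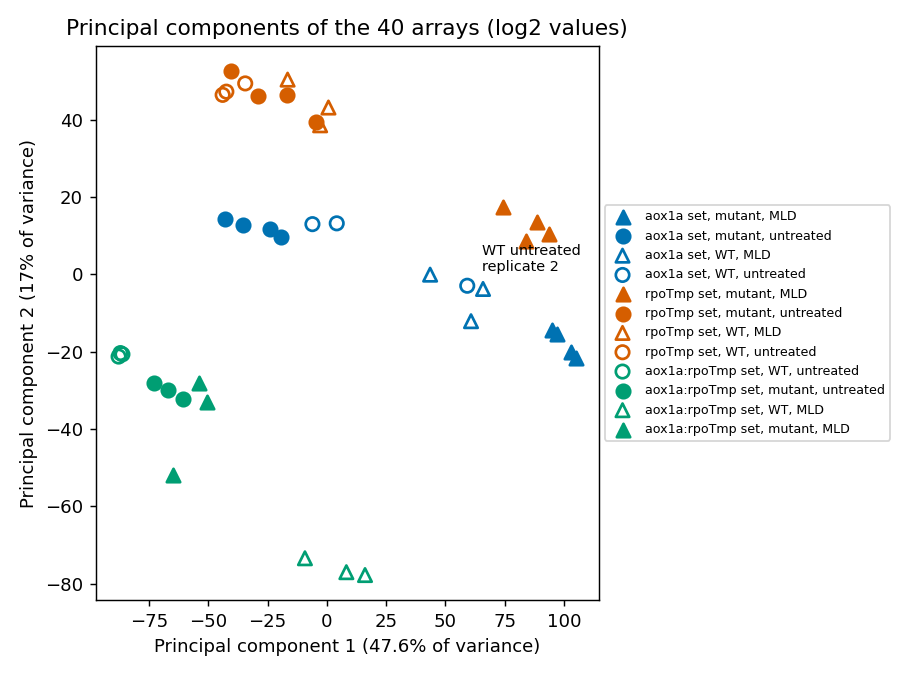
Principal components 1 (47.6% of variance) and 2 (17%) of the 40 arrays, computed from log2 values; each point is an array, colours mark the 3 sets, open symbols wild type, filled symbols mutants, circles untreated plants and triangles MLD. Wild-type untreated replicate 2 of the aox1a set, at 59.23 on component 1, lies among the wild-type MLD arrays of its set (43.57 to 65.89), while the other untreated wild types of that set lie at -6.08 and 4.18.

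The mutated genes gave no firm check of the labels of any mutant, the untreated double mutant included. The table used pairs no probe set with AOX1A. The probe set of RPOTMP (AT5G15700) was dim in every group, with log2 means between 2.48 and 4.28. In the rpoTmp set its log2 mean was 2.84 ± 0.14 (SD, n = 3) in untreated wild type, 2.48 ± 0.09 (n = 2) in line 1 and 2.59 ± 0.15 (n = 2) in line 2. Under MLD these means were 2.85 ± 0.10 (n = 3), 2.58 ± 0.03 (n = 2) and 3.11 ± 0.64 (n = 2). In the double set it read 3.40 ± 0.53 (n = 3) in untreated wild type and 2.56 ± 0.03 (n = 3) in the mutant, and 2.60 ± 0.05 and 2.51 ± 0.02 under MLD. In the aox1a set it read 3.03 ± 0.31 (n = 3) and 3.26 ± 0.45 (n = 3) in wild type, untreated and under MLD, and between 2.53 and 4.28 in the 4 groups of the mutant lines. It rose with MLD in aox1a by 1.60 ± 0.27 (SE, adjusted p = 0.00122), more than in wild type by 1.36 ± 0.42 (adjusted p = 0.0457, and 0.0991 without wild-type untreated replicate 2). It fell with MLD in the wild type of the double set by 0.80 ± 0.20 and was lower in the untreated double mutant by 0.84 ± 0.20 (log2 change -0.84, adjusted p = 0.0172), but not in rpoTmp (adjusted p = 0.556 untreated and 0.998 under MLD).

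MLD raised anthocyanin genes in the wild type of all 3 sets. In the aox1a set UF3GT, a glycosyltransferase of anthocyanin synthesis, rose from a log2 mean of 2.60 ± 0.56 to 10.96 ± 0.84 (SD, n = 3 each; change 8.36 ± 0.41, SE, and adjusted p = 0.000209). DFR, dihydroflavonol reductase, rose by 8.29 ± 0.56, and AT4G14090, an anthocyanin glucosyltransferase, by 6.86 ± 0.59. All 5 measured flavonoid genes rose there, as they did adjusted over the list alone (camera adjusted p = 5.25e-13, and adjusted p = 0.0703 with an estimated correlation). The expansin EXPA8 fell by 5.24 ± 0.95 (adjusted p = 0.0277), AT4G27450 by 3.67 ± 0.24 and CYP71B22, a cytochrome P450, by 3.02 ± 0.29. Of 5 drought and abscisic acid genes 2 rose, LTI30 by 2.23 ± 0.43 and COR15A by 1.97 ± 0.40; 2 passed adjusted over the list alone, and the list call (adjusted p = 0.00319) had an adjusted p = 0.178 with an estimated correlation. Of 6 chlorophyll biosynthesis genes 1 fell, 3 adjusted over the list alone (adjusted p = 0.00479, and adjusted p = 0.297 with an estimated correlation). Altogether 763 probe sets were called, 473 higher and 290 lower. Without wild-type untreated replicate 2 the count was 3119, and leaving out single arrays gave 102 (without MLD replicate 3) to 3119. Without that array 5 of the 6 chlorophyll genes were called lower.

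In the rpoTmp set the wild-type response had 820 probe sets called, 368 higher and 452 lower. UF3GT rose by 4.31 ± 0.59 (SE, n = 3 each, and adjusted p = 0.0106) and AT4G14090 by 3.65 ± 0.50. Of the 5 flavonoid genes 3 passed over all probe sets and 4 adjusted over the list alone (camera adjusted p = 1.34e-06, and adjusted p = 0.230 with an estimated correlation). LHCB4.3, a light-harvesting protein, rose by 1.55 ± 0.22, while AT3G62950 fell by 3.10 ± 0.53 and UGT76C2, a cytokinin glucosyltransferase, fell by 2.07 ± 0.28. NDB2, an external NADH dehydrogenase of mitochondria, was the 1 gene called among 9 of the mitochondrial stress list, here (1.22 ± 0.22) and in the aox1a set (0.83 ± 0.18). Leaving out single arrays gave 127 (without wild-type untreated replicate 1) to 628 calls.

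The wild type of the double set changed most widely, with 9663 probe sets called, 4156 higher and 5507 lower. The calmodulin-like genes CML38 (8.49 ± 0.41, SE, n = 3 each, and adjusted p = 6.9e-07) and CML37 (7.72 ± 0.24) rose, as did the zinc-finger gene STZ (7.06 ± 0.26). DFR rose by 7.97 ± 0.39 and UF3GT by 5.56 ± 0.46; 4 of 5 flavonoid genes rose, also adjusted over the list alone (adjusted p = 0.00156, and adjusted p = 0.204 with an estimated correlation). Of the drought genes 4 of 5 rose, 5 adjusted over the list alone, and of the glucosinolate genes 3 of 3, with UGT74B1 up by 2.76 ± 0.14 (adjusted p = 0.00471 for each list, and adjusted p = 0.204 with an estimated correlation). Of 11 mitochondrially encoded genes 7 rose, also adjusted over the list alone, with cox2 up by 1.93 ± 0.20 (adjusted p = 0.00471, and adjusted p = 0.204 with an estimated correlation). Of 6 chlorophyll biosynthesis genes 5 fell, among them GSA1 by 1.96 ± 0.09, and HEMA2 rose by 3.93 ± 0.31 (adjusted p = 0.0446, and adjusted p = 0.410 with an estimated correlation). The cytokinin response regulator ARR15 fell by 5.04 ± 0.27. The log2 ratio of 3′ to 5′ GAPDH control probe sets, a sign of RNA quality, was 3.60 ± 0.10 (SD, n = 3) in the untreated and 4.02 ± 0.12 under MLD in this wild type. Another GAPDH pair on the arrays read 0.335 to 0.423 untreated and 0.395 to 0.647 under MLD, so its ranges overlapped. Unless stated, GAPDH ratios given below are of the former pair. Response differences between sets were called for 5766 probe sets against the aox1a set, 5947 against the rpoTmp set, and 184 between those sets. For this wild type the labels also give different ages to the treatments.

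**Figure D2:**
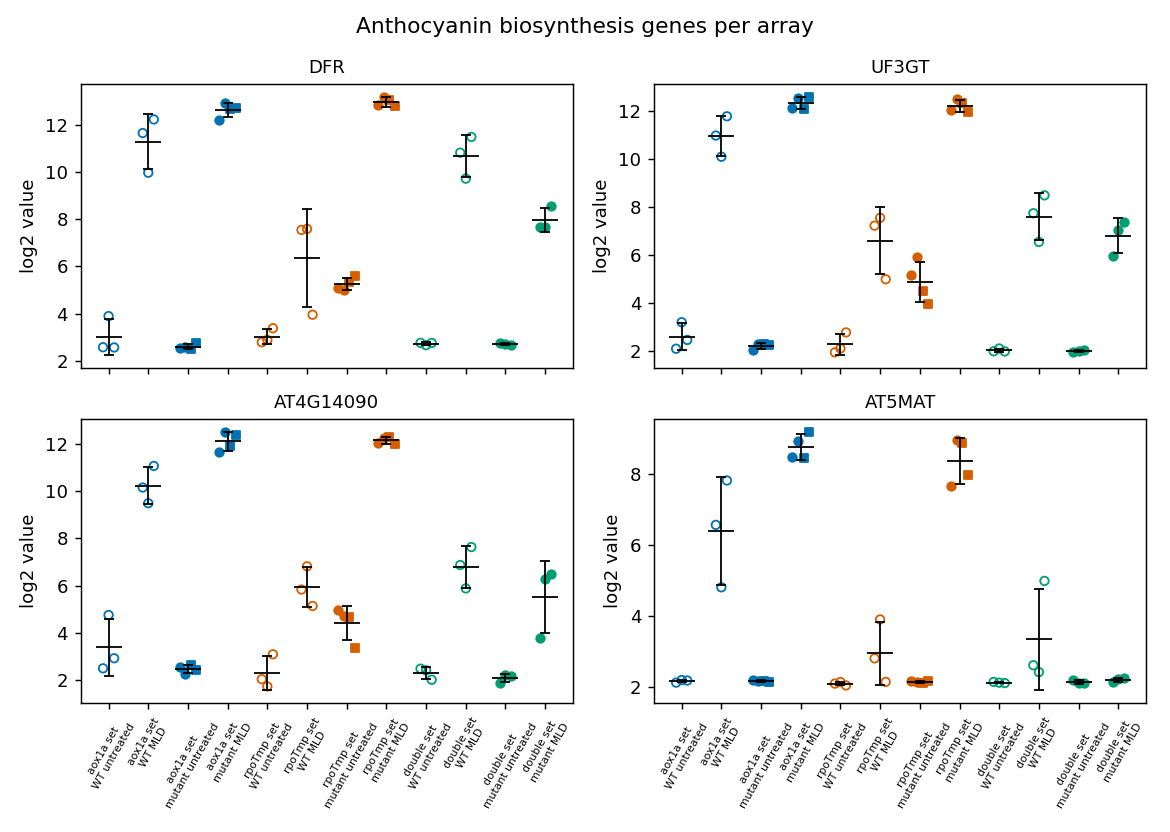
Log2 values of the anthocyanin genes DFR, UF3GT, AT4G14090 and AT5MAT on each array, by set, genotype and treatment; points are arrays (squares, line 2), bars the group mean with its SD over the arrays of a genotype and treatment. UF3GT means under MLD reach 10.96 in the wild type of the aox1a set, 6.60 in that of the rpoTmp set and 7.60 in that of the double set.

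Untreated aox1a plants differed from wild type by a set of calls that rested on single arrays. Of 1557 probe sets called, 745 were higher and 812 lower, and without wild-type untreated replicate 2 the count was 208, of which 184 were among the 1557. With line 2 alone few probe sets were called, and with line 1 alone far more, as given below. AT1G49500 was higher by 4.42 ± 0.65 (SE, 4 mutant and 3 wild-type arrays, and adjusted p = 0.0202), AT4G15700, a glutaredoxin-family gene, by 3.34 ± 0.20, and PDF1.2b, a plant defensin, by 2.61 ± 0.30; AT1G80130 was lower by 2.85 ± 0.32 (log2 change -2.85). Without the replicate these read 3.58 ± 0.45, 3.30 ± 0.24, 2.63 ± 0.36 and -2.44 ± 0.22 and stayed called. PDF1.2 (2.85 ± 0.49) and the linker histone gene HIS1-3 (-2.91 ± 0.58) had adjusted p = 0.0762 and 0.0944 without it. None of the 9 mitochondrial stress genes was called (camera adjusted p = 0.603), nor any of 5 alternative respiration, 7 photosystem or 5 flavonoid genes. Of 9 complex IV genes AT5G57815 was called, with a log2 change of -0.64 ± 0.15, and -0.43 ± 0.09 (adjusted p = 0.0726) without the replicate. The chlorophyll list (0 of 6 called, 4 higher adjusted over the list alone) and the mitochondrially encoded list (0 of 11, 1 lower adjusted over the list alone) had adjusted p = 0.0418 each, and adjusted p = 0.770 with an estimated correlation. Without the replicate these lists had adjusted p = 0.0529 and 0.104. Each of the 7 arrays moved the count by over 1.5 times when left out, to between 156 (without line 2 replicate 1) and 2500 (without wild-type replicate 1).

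Untreated rpoTmp plants showed changes in the signals of mitochondrially encoded genes and in genes known from mitochondrial dysfunction. cox1, the mitochondrially encoded subunit of cytochrome c oxidase, fell by 3.60 ± 0.21 (SE, 4 mutant and 3 wild-type arrays, and adjusted p = 0.000213). cox2 rose by 1.77 ± 0.20, nad1 by 1.32 ± 0.26 and the cytochrome c maturation gene ccb452 by 2.45 ± 0.24. Probe sets of 1 gene did not all move alike. The 7 of nad1 ran from -0.08 ± 0.04 to 2.64 ± 0.49. Of the 2 of nad5, 1 was not called (-0.75 ± 0.39) and the other rose by 1.41 ± 0.24 (adjusted p = 0.0273). AT2G07722 (3.09 ± 0.33) and AT2G07777 (2.35 ± 0.26) also rose and AT2G07718 fell by 2.18 ± 0.39; these loci lie in a nuclear region known to hold a copy of mitochondrial DNA. Of 11 mitochondrially encoded genes 2 rose and 1 fell, 4 and 2 adjusted over the list alone, with a camera adjusted p = 0.959. This list holds cox1, cox2, matR and nad genes only. Since ccb452 is not in it, the count does not cover all mitochondrial genes measured. Of 9 mitochondrial stress genes 3 rose, also adjusted over the list alone: AT5G09570, a twin cysteine protein, by 4.56 ± 0.84, AT2G21640, a gene raised by oxidative stress, by 2.31 ± 0.35, and NDB2 by 1.34 ± 0.20 (adjusted p = 0.00207, and adjusted p = 0.261 with an estimated correlation). The MADS-box genes AGL42 and AGL19 rose by 4.01 ± 0.78 and 3.12 ± 0.56, and QQS, a gene linked to starch content, by 3.53 ± 0.40. No flavonoid gene passed over all probe sets and 3 of 5 did adjusted over the list alone, with UF3GT at 2.60 ± 0.55 (list adjusted p = 0.0024, and adjusted p = 0.261 with an estimated correlation). In all 353 probe sets were called, 205 higher and 148 lower. Omission of any of the 7 arrays moved that count by over 1.5 times, to between 93 (without wild-type replicate 1) and 636 (without line 2 replicate 1).

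The untreated double mutant had the strongest rise of mitochondrial stress genes of the 3 genotypes: 9 of 9 rose, also adjusted over the list alone, with a median log2 change of 5.87 (camera adjusted p = 1.1e-16, and adjusted p = 0.000236 with an estimated correlation). AT2G04050, a MATE-type efflux transporter, rose from 2.85 ± 0.04 to 10.61 ± 0.58 (SD, n = 3 each; change 7.76 ± 0.22, SE, and adjusted p = 2.68e-07). Its wild-type value lies near the floor, so the size of this rise is not exact. AT5G51440, a mitochondrial small heat shock protein, rose by 7.50 ± 0.27 and AT5G09570 by 7.10 ± 0.30. Of 5 alternative respiration genes 3 rose, among them NDB4 by 4.92 ± 0.34 and NDB2 by 3.52 ± 0.22, with 3 higher and 1 lower adjusted over the list alone (adjusted p = 0.0025, and adjusted p = 0.0493 with an estimated correlation); both are also members of the stress list. AT2G04070, another MATE-type transporter outside the lists, rose by 6.86 ± 0.17. Of 9 complex IV genes 6 rose, AT1G53030 by 1.24 ± 0.11, and adjusted over the list alone 6 rose and 1 fell (adjusted p = 0.00113, and adjusted p = 0.203 with an estimated correlation). cox1 fell by 2.16 ± 0.28, while nad9 rose by 2.39 ± 0.25 and cox2 by 2.33 ± 0.20. ARR15 fell by 3.84 ± 0.27 and CYP71B22 by 3.51 ± 0.41. The GAPDH log2 ratio was 3.21 ± 0.07 (SD, n = 3) in the mutant and 3.60 ± 0.10 in its wild type. On the other GAPDH pair they overlapped, at 0.386 to 0.418 in the mutant and 0.335 to 0.423 in the wild type. None of the 5 flavonoid genes was called. Of 69 plastid-encoded genes 1 rose and 13 fell, 1 and 14 adjusted over the list alone (adjusted p = 0.00306, and adjusted p = 0.434 with an estimated correlation). The 4489 calls split into 2303 higher and 2186 lower.

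**Figure D3:**
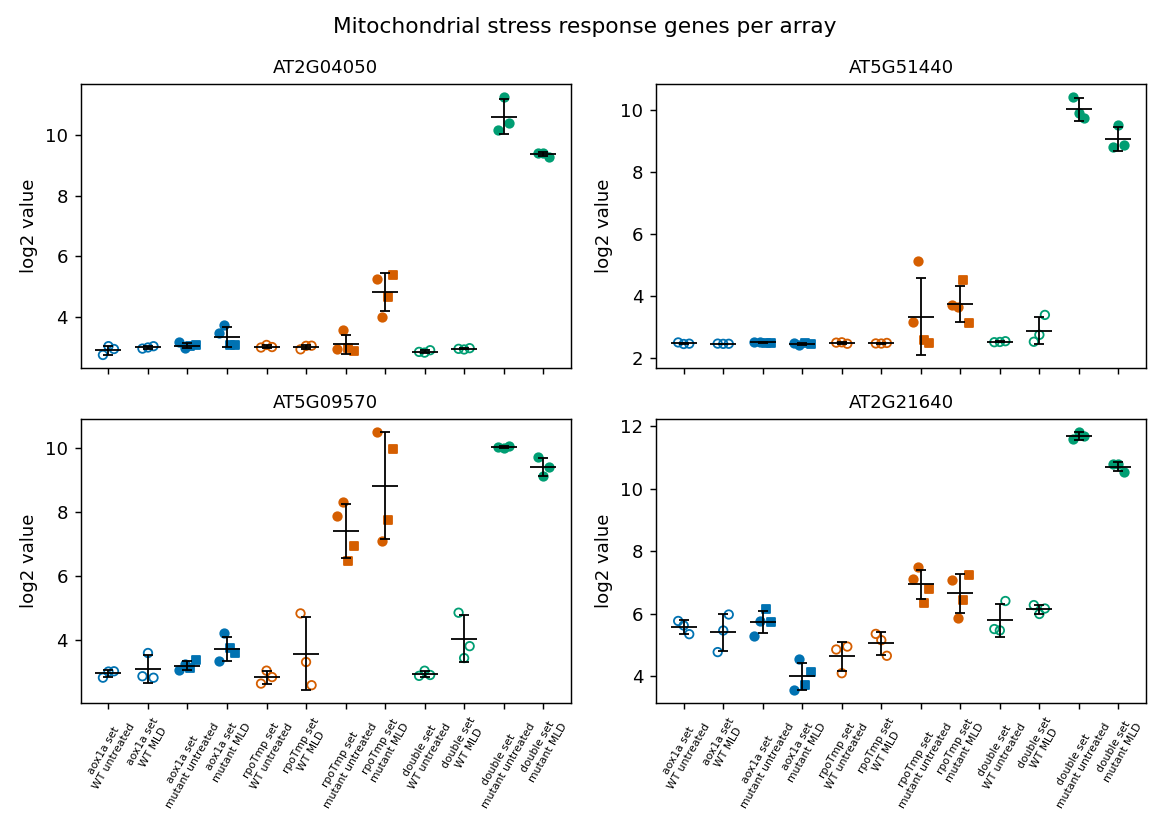
Log2 values of the mitochondrial stress genes AT2G04050, AT5G51440, AT5G09570 and AT2G21640 on each array, by set, genotype and treatment; points are arrays (squares, line 2), bars the group mean with its SD over the arrays of a genotype and treatment. AT2G04050 lies at 10.61 untreated and 9.37 under MLD in the double mutant, against 2.85 and 2.94 in its wild type.

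Under MLD 6 of 7 nuclear photosystem genes and 3 of 6 chlorophyll biosynthesis genes were lower in the aox1a mutant than in wild type. Of 7 nuclear photosystem genes 6 fell, also adjusted over the list alone: LHCB4.2, a light-harvesting protein, by 2.37 ± 0.15 (SE, 4 mutant and 3 wild-type arrays, and adjusted p = 0.000112) and PSAN, a photosystem I subunit, by 1.43 ± 0.15 (list adjusted p = 1.9e-08, and adjusted p = 0.096 with an estimated correlation). Of 6 chlorophyll biosynthesis genes 3 fell, with the protochlorophyllide oxidoreductase PORB down by 1.76 ± 0.43, a drop in CHLM of 1.71 ± 0.27 (log2 change -1.71), and the same count adjusted over the list alone (adjusted p = 0.0109, and adjusted p = 0.473 with an estimated correlation). AT5G22580 fell by 7.07 ± 0.55 and AT5G63180, a pectate lyase, fell by 6.18 ± 0.59. AT1G05340 rose by 4.70 ± 0.20, the kinase WNK9 by 2.85 ± 0.12 and the amylase AMY1 by 2.65 ± 0.50. Of 5 flavonoid genes 2 rose, 4 adjusted over the list alone, with AT5MAT, an anthocyanin acyltransferase, up by 2.36 ± 0.57 (adjusted p = 0.0109, and adjusted p = 0.473 with an estimated correlation). The mitochondrial stress list held 1 gene that rose and 2 that fell, 3 and 2 adjusted over the list alone, among them AT2G21640, which fell by 1.41 ± 0.32. Its median log2 change was 0.01, its mean -0.03, and camera pointed up (adjusted p = 0.717). In all 2819 probe sets were called, 1423 higher and 1396 lower. The count was 4073 without wild-type untreated replicate 2, an array of the fit outside this comparison, 1090 without wild-type MLD replicate 1, 1736 without line 2 replicate 2, and 798 with line 2 alone.

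In rpoTmp under MLD the anthocyanin genes exceeded the wild type and nuclear photosystem genes fell below it. All 5 flavonoid genes were higher, also adjusted over the list alone: DFR by 6.62 ± 0.75 (SE, 4 mutant and 3 wild-type arrays, and adjusted p = 0.000181), AT4G14090 by 6.24 ± 0.46 and UF3GT by 5.61 ± 0.55 (list adjusted p = 7.49e-06, and adjusted p = 0.109 with an estimated correlation). All 7 photosystem genes fell, LHCB4.2 by 2.05 ± 0.39 and PSAN by 1.90 ± 0.17, with the same count adjusted over the list alone and the same p values for the list. Of 6 chlorophyll biosynthesis genes 5 fell, PORB by 3.34 ± 0.34 (adjusted p = 0.000131, and adjusted p = 0.202 with an estimated correlation). Mitochondrial stress genes rose in 6 of 9 cases, 7 adjusted over the list alone, AT5G09570 by 5.24 ± 0.84 (adjusted p = 0.000518, and adjusted p = 0.109 with an estimated correlation). cox1 fell by 2.03 ± 0.21, and cox2 rose by 2.78 ± 0.20. The vacuolar processing enzyme gene BETA-VPE rose by 5.45 ± 0.36 and HIS1-3 by 6.58 ± 0.67, while AT2G10940 fell by 8.87 ± 0.38. There were 6830 calls, 3578 higher and 3252 lower.

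Under MLD most mitochondrial stress genes were higher in the double mutant than in its wild type, and 3 of 5 drought genes were lower. Of 9 mitochondrial stress genes 6 were higher, AT2G04050 by 6.43 ± 0.22 (SE, n = 3 each, and adjusted p = 4.12e-07), and NDB2 fell by 1.19 ± 0.22; the counts were the same adjusted over the list alone (adjusted p = 0.00104, and adjusted p = 0.0424 with an estimated correlation). cox1 fell by 3.96 ± 0.28. Of 5 drought genes 3 fell, 4 adjusted over the list alone, the dehydrins COR47 by 3.22 ± 0.39 and LTI30 by 3.20 ± 0.61 (adjusted p = 0.0402, and adjusted p = 0.398 with an estimated correlation). Of 6 chlorophyll biosynthesis genes 5 rose, GSA1 by 1.46 ± 0.09, while HEMA2 fell by 2.86 ± 0.31 (adjusted p = 0.0402, and adjusted p = 0.398 with an estimated correlation). DFR fell by 2.71 ± 0.39, the 1 flavonoid gene called of 5. Of 8 complex I genes 6 rose and 1 fell (adjusted p = 0.0352, and adjusted p = 0.398 with an estimated correlation). AT5G12340 had the largest fall, a log2 change of -6.82 ± 0.35. The GAPDH log2 ratio was 3.33 ± 0.26 (SD, n = 3) in the mutant and 4.02 ± 0.12 in its wild type. On the other GAPDH pair they overlapped, at 0.298 to 0.605 in the mutant and 0.395 to 0.647 in the wild type. Calls numbered 8176, 4280 higher and 3896 lower.

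Within aox1a, MLD changed 11837 probe sets, 5647 up and 6190 down, and within rpoTmp 7891, 4098 up and 3793 down. In both mutants all 5 flavonoid genes rose, UF3GT by 10.11 ± 0.36 (SE, n = 4 each) in aox1a and by 7.32 ± 0.51 in rpoTmp. The list had adjusted p = 3.46e-05 and 6.29e-06, and adjusted p = 0.478 and 0.226 with an estimated correlation. Of 7 photosystem genes 6 fell in each, LHCB4.2 by 3.00 ± 0.14 and 3.09 ± 0.36 (adjusted p = 0.00231 and 0.000321, and adjusted p = 0.478 and 0.226 with an estimated correlation). In aox1a the other member, LHCB4.3, rose, by 1.19 ± 0.15 in the fit without wild-type untreated replicate 2 (adjusted p = 0.00027). The response exceeded that of wild type, as a test of the interaction, in 2 flavonoid genes of 5 in aox1a and 5 of 5 in rpoTmp, and in 5 each adjusted over the list alone (adjusted p = 0.0209 and 1.69e-05, and adjusted p = 0.661 and 0.194 with an estimated correlation). Without wild-type untreated replicate 2 of the aox1a set, 1 of the 5 was called in aox1a, and UF3GT had an adjusted p = 0.105. In each, 6 of 7 photosystem genes fell further, 6 and 7 adjusted over the list alone (adjusted p = 1.22e-05 and 2.11e-07, and adjusted p = 0.262 and 0.158 with an estimated correlation). AT2G10940 fell further by 6.55 ± 1.11 in aox1a and by 8.14 ± 0.53 in rpoTmp. The interactions called 5093 probe sets in aox1a and 3397 in rpoTmp. The aox1a count was 2580 without wild-type MLD replicate 1, 3306 without line 1 untreated replicate 1 and 1449 with line 2 alone. With line 1 alone the rpoTmp interaction count was 1475. The GAPDH log2 ratio was higher under MLD in both rpoTmp lines. It was 3.70 ± 0.26 against 3.16 ± 0.09 untreated (SD, n = 2) in line 1 and 3.48 ± 0.05 against 3.12 ± 0.13 in line 2. In their wild type it was 3.50 ± 0.31 against 3.20 ± 0.18 (n = 3), and in the aox1a lines it moved in opposite directions.

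The double mutant responded to MLD with 5011 calls, 2313 up and 2698 down. Of the mitochondrial stress genes 7 of 9 fell, GSTU25, a glutathione transferase, by 4.22 ± 0.68 and NDB4 by 2.99 ± 0.34 (SE, n = 3 each; list adjusted p = 0.000447, and adjusted p = 0.0464 with an estimated correlation). The ethylene-response-type factor ORA47 rose by 7.54 ± 0.19 and STZ by 5.73 ± 0.26. Of 5 flavonoid genes 4 rose, DFR by 5.27 ± 0.39 (adjusted p = 0.000202, and adjusted p = 0.220 with an estimated correlation). Against the response of wild type, 9 of 9 mitochondrial stress genes were lower, NDB2 by a log2 difference of -4.71 ± 0.30 (adjusted p = 0.00017, and adjusted p = 0.0236 with an estimated correlation), and 4 of 5 drought genes were lower (adjusted p = 0.0126, and adjusted p = 0.414 with an estimated correlation). This interaction called 7425 probe sets, 3814 higher and 3611 lower.

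The double mutant was set against each single mutant by comparing their effects. Untreated, 8 of 9 mitochondrial stress genes (9 adjusted over the list alone) had a higher effect in the double mutant than in rpoTmp (adjusted p = 1.51e-23, and adjusted p = 7.83e-07 with an estimated correlation) and 9 of 9 than in aox1a (adjusted p = 9.75e-19, and adjusted p = 5.59e-06 with an estimated correlation). Without wild-type untreated replicate 2 of the aox1a set, 8 of 9 were called against aox1a. AT2G04050 differed by 7.69 ± 0.32 and 7.61 ± 0.32 (SE, 40 arrays). Of the 5 alternative respiration genes 3 were higher in each case (adjusted p = 7.01e-06 and 0.000358, and adjusted p = 0.000277 and 0.00249 with an estimated correlation). The untreated cox1 effect was higher than in rpoTmp by 1.44 ± 0.36 and lower than in aox1a, a difference of -1.40 ± 0.36. Under MLD it was lower than in both, with differences of -1.92 ± 0.36 and -4.57 ± 0.36. Untreated cox1 stood at 5.29 ± 0.23 (SD) in the wild type of the double set and 3.13 ± 0.43 in the double mutant, against 7.63 ± 0.16 in the wild type of the rpoTmp set, which leaves less room for a fall in the double set. Under MLD all 5 flavonoid genes had a lower effect in the double mutant, DFR by -9.33 ± 0.87 against rpoTmp (list adjusted p = 7.68e-05, and adjusted p = 0.184 with an estimated correlation) and -4.06 ± 0.87 against aox1a (adjusted p = 0.0109, and adjusted p = 0.236 with an estimated correlation). Photosystem genes had a higher effect, 7 of 7 against rpoTmp (adjusted p = 6.84e-05, and adjusted p = 0.184 with an estimated correlation) and 6 of 7 against aox1a (adjusted p = 3.5e-05, and adjusted p = 0.0865 with an estimated correlation), with PSAN at 2.32 ± 0.22 and 1.85 ± 0.22. Calls untreated and under MLD were 2154 and 9539 against rpoTmp, and 5410 and 7499 against aox1a. The MLD differences also carry the wild-type responses, which differed between the double and rpoTmp sets for 5947 probe sets. Between the double and aox1a sets they differed for 5766. Genotype and the response of each wild type cannot be told apart in these differences. Of the 85 list calls with the preset correlation in the 19 comparisons, 10 held with an estimated correlation, all of them for the mitochondrial stress and alternative respiration lists in comparisons of the double mutant.

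The effects of the single mutants under MLD overlapped. Of the probe sets called in both, 638 were higher in both (224 expected by chance) and 827 lower in both (200 expected), and the log2 changes had r = 0.667 across probe sets, which are not independent replicates. Their interactions shared 853 higher and 922 lower (196 and 181 expected), with 17 opposite (384 expected) and r = 0.755. The interaction of the double mutant ran opposite to both, with 1944 opposite calls against aox1a (829 expected; r = -0.395) and 1745 against rpoTmp (556 expected; r = -0.394). Each interaction subtracts the wild-type response of its set (9663 calls in the double set, 763 and 820 in the aox1a and rpoTmp sets). Between the mutant stress responses themselves r was 0.0999 for aox1a and 0.00889 for rpoTmp, each against the double mutant. Opposite calls there were 1596 (1300 expected) and 1440 (872 expected), and calls in the same direction also exceeded those expected. How far the opposite sign comes from the wild-type responses was not tested. Untreated, rpoTmp and the double mutant shared 108 higher and 33 lower (20.8 and 14.2 expected; r = 0.213). Untreated aox1a ran opposite to both, with 375 opposite calls against the double mutant (154 expected, r = -0.241) and 34 against rpoTmp (12.2 expected, r = -0.347). Under MLD the double mutant ran opposite to rpoTmp, with 3325 opposite calls (1220 expected, r = -0.351). With aox1a it shared 383 higher and 305 lower (268 and 239 expected) and had 743 opposite (506 expected, r = -0.116). These effects under MLD are also taken against wild types whose responses differed between sets. Without wild-type untreated replicate 2 of the aox1a set the untreated opposite calls of aox1a fell to 64 (20.5 expected, r = -0.185) and 7 (1.58 expected, r = -0.311). Without that replicate, the r between the single-mutant interactions was 0.723. No arrays are shared between the sets compared here.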

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

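All tests of the replicate that lies apart, the test of array-wide scale and the test against the sum of the single effects were chosen after the result was seen; counts over other splits of the arrays, the test of plant age and that of the wild-type level were not.

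The stress response differed between genotypes in all 3 sets, by a test of the interaction: 5093 probe sets in the aox1a set, 3397 in the rpoTmp set and 7425 in the double set. The effect of the double mutant differed from that of rpoTmp for 2154 probe sets untreated and 9539 under MLD, and from that of aox1a for 5410 and 7499. The wild-type response differed between the rpoTmp and aox1a sets for 184 probe sets, between the double and aox1a sets for 5766 and between the double and rpoTmp sets for 5947.

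Wild-type untreated replicate 2 of the aox1a set lies with the MLD arrays of its set. A swap with a wild-type MLD array is argued against: on a mean of 613 probe sets called in the wild types of both other sets, the lowest of the 3 wild-type MLD arrays stood 0.794 above the higher of the other untreated arrays. On the same score the array stood at 0.578 and the wild-type MLD arrays at 0.712 to 0.924 (SD 0.121), which left a single mislabelled MLD array barely separated, so the 5 flavonoid genes were then used: its mean was 4.09, against 8.64 to 10.8 in the MLD arrays and 3.02 and 3.23 in the other untreated arrays, and the gap of -4.54 argues against that label error. A mixture with a wild-type MLD sample of its set is argued against, since all 6 computed mixtures of such arrays with the stress score of the array (67 to 88% MLD) had a flavonoid mean of 8.18 to 10.3 (SD 0.942), at least 4.087 above it, and lower RNA quality by its GAPDH log2 ratio of 3.144, within 2.69 to 3.92 of the other 13 arrays. A plant that was partly stressed may account for it and was not tested.

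The wild-type response was larger in the double set (9663 calls) than in the aox1a and rpoTmp sets (763 and 820). An array-wide scale of the deposited values is argued against, since quantile normalisation gave 9682 calls there and 733 and 845 in the others. The age difference between untreated and MLD plants, given by the sample characteristics alone, may contribute and cannot be told apart from the set. The double mutant, with the same ages in those characteristics, moved 61.1% of those probe sets the same way, which lies between the bounds set for that test. This mutant also received MLD, so the stress itself can move them the same way and the test cannot decide on age. The growing occasion, the array batch and the strength of the stress stay open as well, untested.

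The mitochondrial stress genes of the untreated double mutant exceeded the sum of the single effects: 9 of 9 measured members had an excess above 0 adjusted over the list alone, and 8 over all probe sets, with a median excess of 3.99 on the log2 scale. Without the replicate in doubt 9 of 9 did so. For members near the floor in wild type, such as AT2G04050, the size of the excess is not exact. A rise in a single mutant that stays below the floor is not subtracted, so the excess can be overstated. A lower wild-type level in the double set is argued against for the list, as the median level there differed from the other sets by 0.045, though NDB2 alone stood 1.61 lower (difference -1.61). Under MLD 5 of the 9 lay above the sum and 2 below. That the combined mutation raises these genes beyond the sum may be a hypothesis for follow-up; plant age, which the growth protocol gives as 6 to 7 weeks for the double mutant and 4 for its wild type, stays open.

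Other splits of the arrays, with lines pooled, gave fewer calls than the real split for most counts, given here as the real count and the highest of the other splits: aox1a untreated 2519 and 540, aox1a under MLD 3055 and 840, aox1a response 12024 and 1, aox1a interaction 5431 and 376, rpoTmp untreated 262 and 163, rpoTmp under MLD 6578 and 3374, rpoTmp response 7669 and 4, double interaction 7425 and 6638, double against rpoTmp under MLD 9436 and 6302, and double against aox1a 5362 and 3544 untreated and 7377 and 5679 under MLD. In each of these 1 split, the real one, gave as many. Splits numbered 35 for the untreated, MLD and response counts of the single mutants and 100 for the others. With 35 splits, 1 of 35 is the lowest share possible, and no correction was made over the comparisons. The splits do not guard against a single deviating array, and the untreated aox1a and rpoTmp counts moved with single arrays, as given below. Splits with counts such as 6638 and 6302 keep a true grouping of a set and treatment or its mirror, so they are not free of the real difference. The highest of the rest was 1 for the double interaction and 3447 for double against rpoTmp under MLD. For double against aox1a it was 17 untreated and 354 under MLD. For the rpoTmp interaction (3004) 3 of 100 splits were as large, the real one included. The highest other, 5293, and the other larger one keep a true grouping or its mirror, and the highest of the rest was 265. For the double mutant against rpoTmp untreated (2023) chance is not excluded, as 7 of 100 splits gave as many, up to 3171; the other 6 keep or mirror a true grouping in a set, and the highest of the rest was 217. The 10 splits of 6 arrays are too few for the wild-type responses (955 and 401, 646 and 3, 9663 and 0 in the aox1a, rpoTmp and double sets) and for the double mutant untreated (4489 and 3), under MLD (8176 and 1) and in its response (5011 and 1).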

How the results depend on the processing

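All alternatives were planned, except list tests and overlaps without wild-type untreated replicate 2 of the aox1a set, which were chosen after the data were seen. No result reversed its direction. Trend and robust moderation kept all 19 counts within 1.5 times. Beyond that factor, quantile normalisation moved 1 of 19, the filter on dim probe sets 1 of 19, array weights 5 of 19, the fit of all 40 arrays 4 of 15, pooled lines 1 of 12, line 1 alone 3 of 12, line 2 alone 5 of 12, and omission of 1 array 29 of 172. The cause was not tested, except that a single line or an omitted array leaves fewer arrays.

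Untreated aox1a (1557) became 652 with quantile normalisation, 2405 with array weights, 3745 in the fit of all 40 arrays, 2519 with pooled lines, 936 with line 1 and 11 with line 2. Untreated rpoTmp (353) became 888 with array weights, 937 in the fit of all 40 arrays and 97 with line 2. Aox1a under MLD (2819) became 5268 with array weights and 798 with line 2. The wild-type response became 3835 with array weights and 1986 in the fit of all 40 arrays in the aox1a set, and 2111 and 1620 in the rpoTmp set. The aox1a response (11837) became 7667 after the filter on dim probe sets, which tests fewer probe sets, and 6992 with line 2; the aox1a interaction became 1449 with line 2. With line 1 the rpoTmp response (7891) became 4682 and the interaction 1475.

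With a replicate block, the counts were 333 and 453 for the wild-type responses of the aox1a and rpoTmp sets, 1768 for aox1a under MLD and 96 for untreated rpoTmp. The replicate numbers showed no clear pairing of the arrays. Residuals of same-numbered arrays had a median r of 0.0626, 0.0118 and 0.0362 in the aox1a, rpoTmp and double sets. Other-numbered arrays had -0.0302, 0.0188 and -0.0449. In the aox1a set same-numbered pairs ran from -0.438 to 0.59, so some pairing is not excluded.

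Omission of each array compared gave ranges of 102 to 3119 for the wild-type response of the aox1a set, 156 to 2500 for untreated aox1a, 1090 to 2457 for aox1a under MLD, 2580 to 5422 for its interaction, 127 to 628 for the wild-type response of the rpoTmp set and 93 to 636 for untreated rpoTmp. The single arrays that moved a count were, for the aox1a wild-type response, MLD replicates 1 (153) and 3 (102) and untreated replicates 1 (115), 2 (3119) and 3 (156). For untreated aox1a they were line 1 replicates 1 (267) and 2 (587), line 2 replicates 1 (156) and 2 (2361), and wild-type replicates 1 (2500), 2 (208) and 3 (180). For aox1a under MLD they were line 2 replicate 2 (1736) and wild-type MLD replicates 1 (1090) and 3 (1795), and for its interaction line 1 untreated replicate 1 (3306) and wild-type MLD replicate 1 (2580). For the rpoTmp wild-type response they were MLD replicates 1 (194) and 2 (181) and untreated replicates 1 (127), 2 (449) and 3 (306). For untreated rpoTmp they were line 1 replicates 1 (205) and 2 (133), line 2 replicates 1 (636) and 2 (187), and wild-type replicates 1 (93), 2 (155) and 3 (128). Omissions in the other comparisons stayed within 1.5 times. Without wild-type untreated replicate 2, which is in the fit but not in the comparison, aox1a under MLD had 4073 calls. Where an omission leaves 1 array in a line, that array is taken to vary like the other groups.

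Of 85 list calls with the preset correlation, 10 held with an estimated one. Fry, which tests whether the genes of a list move one way, lost 18 calls and gained 40 of 228. Without the replicate in doubt 6 of 72 list results lost their call and 1 gained it. For the named genes, 16 of 732 values lost their call with array weights, 26 with quantile normalisation, 11 with trend and robust moderation, 9 of 569 with the filter on dim probe sets, 62 of 732 with the replicate block, 25 of 588 in the fit of all 40 arrays, 12 of 451 with pooled lines, 55 of 451 with line 1, 114 of 451 with line 2, and 716 of 6522 on omission of an array. Signal near the floor limits dim probe sets such as that of RPOTMP.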

Other observations

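The tests of the gene families were planned; the probe set with the largest fall was singled out after its values were seen.

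Lists with fewer than 3 measured members hold single genes that changed. GI, a circadian clock gene, rose by 2.11 ± 0.25 (SE, adjusted p = 0.000234) in rpoTmp under MLD and fell by 0.93 ± 0.16 in the untreated double mutant. WRKY53, of the salicylic acid list, rose in the wild type of the double set under MLD (2.83 ± 0.47) and in the untreated double mutant (1.78 ± 0.47). AGL24, a flowering regulator, fell by 0.93 ± 0.17 in the untreated double mutant and was higher by 0.86 ± 0.17 under MLD. PDF1.2, a defensin of the jasmonate response, fell by 3.32 ± 0.98 in rpoTmp under MLD and rose by 3.56 ± 0.85 in the double mutant under MLD. STZ, of the oxidative and high light list, rose by 3.16 ± 0.61 in rpoTmp under MLD, and AT3G28580 of the same list by 1.78 ± 0.28 in the untreated double mutant. The small heat shock gene ATHSP22.0 was called in none of the mutant comparisons with wild type, with -0.05 ± 0.04 in rpoTmp under MLD. The import genes AT5G41685 and AT2G19080 rose in rpoTmp under MLD by 0.45 ± 0.10 and 0.42 ± 0.13. The guard cell gene FMA was not called against wild type in any mutant, with values between -0.59 ± 0.17 (adjusted p = 0.0556) and 0.62 ± 0.25 (adjusted p = 0.0867). Organellar transcription was represented by RPOTMP alone. Lists of senescence, floral organs, dividing cells and phloem had 0 measured members, so these cell types were not analysed here.

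Plastid-encoded genes changed in both directions. In aox1a under MLD 15 of 69 fell, petG by 1.78 ± 0.38, and 4 rose, rbcL by 0.94 ± 0.25 (adjusted p = 0.482 with an estimated correlation). In rpoTmp under MLD 14 fell and 6 rose, with rbcL up by 1.46 ± 0.20, and in the double mutant under MLD 9 fell and 17 rose, with rps15 up by 1.45 ± 0.17, a list median of -0.02, a mean of 0.08 and a camera adjusted p = 0.705. Of the 3 genes on the carbon fixation and electron transport list, RCA rose by 0.19 ± 0.04 in aox1a under MLD. ATPC1 fell by 0.31 ± 0.08 in rpoTmp under MLD. The glucosinolate genes AT2G31790 and UGT74B1 fell in rpoTmp under MLD by 0.69 ± 0.12 and 0.51 ± 0.15.

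Gene families fixed by the stem of their symbols were tested for shifts between mutant and wild type and in the wild-type stress responses. Of 189 tests over 21 families, camera in limma called 0 with an estimated and 0 with the preset correlation.

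The lowest mean log2 change in aox1a over both treatments, -4.86, was in a probe set for which no gene is listed; other probe sets fell further under MLD alone. Its log2 change was -5.03 ± 0.56 (SE, adjusted p = 0.00906) untreated and -4.70 ± 0.56 under MLD. In the double mutant it was -0.10 ± 0.25 (adjusted p = 0.857) untreated, where its wild type stood at 5.96 ± 0.33 (SD, n = 3), and -4.83 ± 0.25 under MLD, where its wild type stood at 9.66 ± 0.11. Untreated wild types of the aox1a and rpoTmp sets stood at 9.67 ± 0.34 and 7.23 ± 0.31, untreated aox1a lines at 5.83 (4.94 and 6.73, n = 2) and 3.45 (2.60 and 4.29, n = 2) and the untreated double mutant at 5.87 ± 0.35. The absent difference in the untreated double set thus goes with a wild type that stood lower there than in the other sets. As no gene is listed for this probe set, it gives no check of the labels of these arrays. In rpoTmp it was 1.16 ± 0.24 (adjusted p = 0.053) and 1.99 ± 0.24.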
